A study of Dehalococcoides mccartyi 195 with 8 samples.

How the data were processed

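RNA of the mixed community Donna II was compared on 8 two-colour custom arrays designed around *Dehalococcoides mccartyi* strain 195. Per the labels, each array held the RNA of a sample labelled with Cy5 and a common reference pool labelled with Cy3, the pool being RNA from the reactor fed tetrachloroethene (PCE) after 3 days of starvation. The 6 samples fed 1,2,3,4-tetrachlorobenzene (TeCB) are biological replicates, 3 for each of 2 sampling times. The 2 control arrays are technical replicates with the pool in both channels, described in the labels as a dye swap. Each TeCB sample came, per the labels, from 50 mL of culture extracted in 8 portions that were recombined.

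The authors scanned the arrays with Agilent Feature Extraction 10.5 (10.5.1.1 per the file headers). The deposited scanner files give, for each spot and channel, the median pixel intensity, the median intensity of the local background, the scanner's processed intensity after background subtraction and dye normalization, and marks for saturation, outliers and signal well above background. They also hold, per the file headers, a log10 ratio of the processed Cy5 over the processed Cy3 signal. The authors' own table holds processed Cy5 intensities averaged geometrically over the spots of each probe. Which tools the authors used for their statistics is not given in the sources used here.

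From the files, ratios were computed in R 4.3.3 with limma 3.58.1, the packages data.table (version 1.17.8) and jsonlite (version 2.0.0). Median intensities were corrected with limma's normexp method (offset 50), since the files hold no mean intensities, which had been planned. Log2 ratios of Cy5 over Cy3 were normalized within arrays by loess, with control spots and spots marked as outliers at weight 0. The 9 to 25 spots of each probe were averaged; since the files give 1 probe name per gene, nothing remained to be averaged over probes. A probe counted as detected on an array when over 50% of its spots were well above background in Cy5, a majority rule set once the number of spots per probe was known. Probes detected on every array of at least 1 group were tested, which left 1232 probes of strain 195 (1186 loci and 46 stable RNA probes), with 324 of the 1510 loci too dim, and 61 of 64 probes for other community members.

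The 2 control arrays were averaged into 1 sample, and limma was fitted to group means over 7 samples with its moderated variances, so that the replicates of both times set the spread of the control comparisons too. The comparisons were 2 days with the control, 3 days with the control, and 3 days with 2 days, the last also serving as the test of whether the change from the control differed between the times. P-values were adjusted by the Benjamini-Hochberg method over the 1232 strain 195 probes and separately over the 61 community probes, with a threshold of 0.05 for adjusted p; counts with a fold of at least 2 are given beside. Where a probe was not well above background in any sample of a group, its fold was replaced by a bound ("at least N-fold"). The bound was computed from Cy5 signals after quantile normalization across arrays of the log2 intensity averaged over both dyes. Each dim value was raised to that of the dimmest detected probe on its array. No bound is given where the measured signal already reached that limit or the fitted fold was smaller. With no balanced dye swaps, that bound is open to dye bias. The overlap of the 2 control comparisons was set beside 100 simulations of unchanged groups that share 1 control sample.

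The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Of 20 fixed lists, 3 had locus tags written down in advance and could be used (18 reductive dehalogenases, 26 hydrogenase subunits and 3 formate dehydrogenase-like loci); the other 17 relied on product names, which the files do not give. The 64 probes taken to stand for other community members formed a further list. Lists were tested against all other genes with limma's camera at its preset correlation, and again with an estimated correlation, with adjustment over the 4 lists. Genes were named by this rule: for each control comparison, the 6 largest rises and the 6 largest falls past the threshold with all 3 replicates on one side of the control, every reductive dehalogenase, hydrogenase and formate dehydrogenase-like members past the threshold, and up to 2 rising and 2 falling members of each other list with at least 3 members past the threshold or a list call. For 3 days against 2 days the rule took the 5 largest rises and 5 largest falls without overlap between the replicates, and every reductive dehalogenase past the threshold. Not all genes that the rule picked are printed, because their locus tags carry no names. Transfer and ribosomal RNA probes as groups, the stretches DET1556 to DET1560 and DET0251 to DET0254, and community probes beyond the rule were chosen after their values were seen.

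Alternatives covered background correction, the offset (10), the scanner's processed ratios, median centring, scaling between arrays, the Cy5 channel alone, filters on dim probes, the summary over spots, the variance model, the samples in the fit, a replicate block, the use of the control arrays, the authors' table, and leaving out each array in turn. The Cy5 channel alone used the scanner's processed signal with quantile normalization across arrays. The authors' table holds that same signal averaged over spots, so these 2 settings are not independent. Slide row as a covariate, each row alone, a loess on strain 195 loci only and outlier spots kept were added after the data had been seen. All arrays were hybridised on 1 slide, with the 2-day samples and replicate 1 of 3 days in row 1 and the remaining samples of 3 days and both control arrays in row 2. The fit was tested on simulated data, over 20 runs with 200 changed genes. A log2 change of 1 was recovered for 91.2% of genes at 2 days, 90.7% at 3 days and 97.9% between the times. Of the simulated calls, 4.11%, 4.57% and 4.74% were false in that order. Those shares need not hold for the real calls. The spread of the control, a single sample, was assumed to equal that of the TeCB samples and could not be measured. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.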

Results

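Transcript levels were measured by two-colour microarray in Donna II, a mixed anaerobic community that holds *Dehalococcoides mccartyi* strain 195, a bacterium that respires chlorinated organic compounds, alongside fermenting bacteria and methanogens. Subcultures of 100 mL that had starved for 3 days received 1,2,3,4-tetrachlorobenzene (TeCB, 40 µL of a 100 mM solution in hexadecane). The same bottles were given 1 µL of tetrachloroethene (PCE), 40 µL of butyrate, 100 µL of yeast extract and 100 µL of a vitamin solution. Biological replicates were sampled 2 days after feeding (n = 3) and 3 days after feeding (n = 3). The control was 1 RNA pool from the PCE-fed reactor after 3 days of starvation, hybridised on 2 technical arrays and counted as 1 sample. The titles of the TeCB samples give 1 and 2 days, whereas their sampling times and the design text give 2 and 3 days, which are used here. No bottle received the other additions without TeCB, so each comparison with the control sets TeCB plus feeding against starvation. It also sets bottled subcultures given hexadecane against the reactor, and these differences cannot be told apart from TeCB.

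The array held 1627 probes, of which 1510 targeted loci of strain 195 and 46 its stable RNAs. A further 64 were taken to stand for other members of the community. Some of these carry KB1 in their names, such as geobacterkb1 and sporomusakb1, and whether those organisms live in Donna II is not shown. Median Cy5 intensity over spots was 808.5, 763 and 1084 in the 2-day samples, 699, 988 and 801.5 in the 3-day samples, and 653 and 493 in the control arrays, against local backgrounds with medians of 57.5 to 62. Between 1071 and 1269 strain 195 loci were well above background in Cy5 on each array, and 0 spots were saturated. Across loci, which are not independent replicates, log2 ratios correlated with r of 0.783 to 0.936 among 2-day replicates, 0.897 to 0.964 among 3-day replicates and 0.721 to 0.818 between the times. Replicate 3 of 2 days had the widest spread of log2 ratios over loci of all 8 arrays (SD 0.847, against 0.222 to 0.654 in the other 7). The number of arrays limits the precision of every value given here. The files do not pair locus tags with product names, so beyond the lists fixed in advance only a few locus tags are given for each comparison.

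The comparison of 2 days with the control asked which genes of strain 195 differed in level after TeCB and feeding. The largest rise of a strain 195 probe belonged to the reductive dehalogenase DET1559, at 30.0-fold (log2 4.91 ± 0.35 SE, n = 3 against 1 pooled sample, adjusted p = 1.2e-04), followed among these enzymes by DET0180 at 11.4-fold (3.51 ± 0.27, adjusted p = 1.6e-04). DET0079, the trichloroethene reductive dehalogenase TceA, rose 6.11-fold (2.61 ± 0.64, adjusted p = 0.0187), and DET0318, the PCE reductive dehalogenase PceA, stood at 0.13 ± 0.20 (adjusted p = 0.629), or at -0.024 with median centring in place of loess and -0.24 after scaling between arrays. All 5 probes with the consecutive locus tags DET1556 to DET1560, a stretch that includes DET1559 and was singled out after its values were seen, rose by log2 1.73 to 4.91. The deepest fall of a locus was that of DET1532, whose level was 15.7-fold lower (-3.97 ± 0.19, adjusted p = 2.3e-05). Control arrays had a mean log2 ratio of -0.14 for DET1559, -0.12 for DET0180, 0.12 for DET0079 and -0.082 for DET1532. In 3 of 3 samples of 2 days the first 3 of these lay above both control arrays, and DET1532 lay below them. The naming rule took the largest changes only with all replicates on 1 side of the control mean, so this lends no support.

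Of the 18 reductive dehalogenases on the array, 9 were bright enough to test at 2 days: 4 rose (DET0079, DET0173, DET0180 and DET1559), 2 fell (DET0088 and DET0306) and 3 did not pass. The same 4 rose and 2 fell adjusted over the list alone. DET0173 rose 1.95-fold (0.96 ± 0.25, adjusted p = 0.0218), a call lost without replicate 2 of 2 days (0.92). DET0088 was at least 1.42-fold lower and DET0306 at least 1.48-fold lower than in the control, bounds used because neither was well above background in any 2-day sample (adjusted p = 0.0148 and 0.00687). Without control arrays, with ratios set against 0, both were fitted short of their bounds (-0.36 and -0.561, against log2 -0.50 and -0.563). DET1545 (0.66 ± 0.33) and DET1535 (-0.47 ± 0.39) did not pass, although DET1545 passed without replicate 2 of 2 days (0.94) and DET1535 without replicate 1 (-0.78). The list as a whole had a median log2 difference of 0.66 and did not pass (adjusted p = 0.179, and adjusted p = 0.420 with an estimated correlation). With slide row as a covariate its median was 0.63, and over all 18 members, with no filter on dim probes, it was -0.069. The plot of reductive dehalogenases by array shows the values of each sample.

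**Figure D1:**
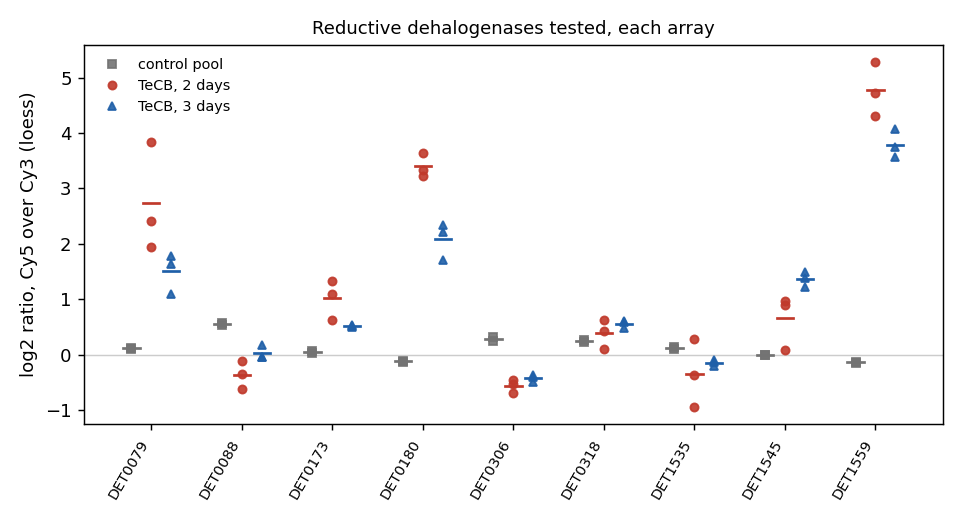
Log2 ratio of Cy5 over Cy3 after loess (vertical axis) for the 9 reductive dehalogenases tested (horizontal axis), with grey squares for the 2 control arrays, red circles for the 3 samples of 2 days, blue triangles for the 3 samples of 3 days and bars for group means. DET1559 and DET0180 lie above the control arrays in all 6 TeCB samples, with DET1559 at a mean of 4.77 at 2 days and 3.79 at 3 days.

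Among 17 hydrogenase subunits tested at 2 days, DET0615 rose (0.81 ± 0.18, adjusted p = 0.0141), DET0728 (-0.48 ± 0.15, adjusted p = 0.0401) and DET0860 (-0.59 ± 0.19, adjusted p = 0.0464) fell, and 14 did not pass. Adjusted over the list alone 1 rose and 0 fell (limma; 3 rose and 2 fell at an unadjusted level of 0.05). The call of DET0728 ended without replicate 1 or 2 of 2 days or without replicate 2 or 3 of 3 days (-0.46 to -0.49). That of DET0860 ended without any of these 4 samples or without control array 2 (-0.52 to -0.61). The median of the hydrogenases was 0.36 (adjusted p = 0.343, and adjusted p = 0.741 with an estimated correlation), or 0.43 with slide row as a covariate, 0.14 without replicate 3 of 2 days and 0.14 over all 26 with no filter on dim probes. Of the 3 formate dehydrogenase-like loci, DET0186 (1.17 ± 0.35, adjusted p = 0.0351) and DET0187, annotated as a formate dehydrogenase alpha subunit (1.38 ± 0.31, adjusted p = 0.0151), rose and DET0185 fell (-0.59 ± 0.16, adjusted p = 0.0249), with the same counts adjusted over the list alone. DET0185 missed the threshold without replicate 2 of 2 days or replicate 3 of 3 days (-0.56 and -0.59), and DET0186 without replicate 2 of 2 days or any 1 sample of 3 days (1.17 to 1.20). The list of 3 had a median of 1.17 (adjusted p = 0.396, and adjusted p = 0.741 with an estimated correlation), or 1.35 with slide row as a covariate. The calls of DET0728, DET0860, DET0185 and DET0186 ended in the Cy5 channel alone and in the authors' table, which hold the same processed signal. Over all settings their values came as near to 0 as -0.32, -0.27, -0.068 and 0.77.

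Of 41 transfer RNA probes of strain 195, 33 fell at 2 days, 1 rose (tRNA-Thr-1, 0.73 ± 0.19, adjusted p = 0.0208) and 7 did not pass, with a median log2 difference of -1.08. tRNA-Ala-1 fell by 3.05 on the log2 scale (SE 0.16, adjusted p = 2.3e-05) and tRNA-Val-2 stood at -2.76 ± 0.15 (adjusted p = 3.4e-05). tRNA-Lys-1, not well above background in any 2-day sample, was at least 7.59-fold lower than in the control (adjusted p = 2.3e-05), though fitted at -2.38, short of that bound (log2 -2.92), after scaling between arrays. tRNA-Ser-1, not well above background at 2 days either, fell too (adjusted p = 2.3e-05), but its signal gave no bound for the fold. The 16S, 23S and 5S ribosomal RNA probes also fell (-1.06, -1.42 and -2.17), as did the probe for the RNA of ribonuclease P (-1.42). The transfer-messenger RNA probe stood at -0.044 and did not pass.

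Among 61 probes tested for other community members, 8 rose, 12 fell and 41 did not pass at 2 days. Hyd_MvH1-MHU, NiFe_LargeSubunit1-MHU and FdhA_1-MHU, named in the files for hydrogenase and formate dehydrogenase genes, were at least 49.9-fold, at least 16.8-fold and at least 4.74-fold higher than in the control (adjusted p = 7.0e-04, 1.1e-05 and 7.6e-04), where none of the 3 was well above background. After scaling between arrays and with median centring the fitted log2 values of the first (4.55 and 5.58) and the second (3.04 and 3.92) lay below those bounds (log2 5.64 and 4.07), as did that of the second without replicate 1 of 2 days (4.01). Other probes with the suffix MHU did not rise: FdhA_2-MHU stood at -0.67 ± 0.23 (adjusted p = 0.0551) and NiFe_LargeSubunit2-MHU at 0.30 ± 0.32 (adjusted p = 0.439). Hyd_F420_1-MHU and Hyd_F420_2-MHU were too dim to test. Of 5 ribosomal probes for Syntrophomonas, those named Syntrophomonas_sp and Syntrophomonas_sp2, of a genus that oxidises butyrate in partnership with hydrogen consumers, rose by log2 1.73 ± 0.25 and 1.72 ± 0.25 (both adjusted p = 0.00183), and the other 3 did not pass (0.30, -0.37 and -0.53). Neither rise was followed under the alternatives. Of 2 further probes, whose names give syntrophomonads beside a second, truncated name, 44_D2CL_Syntrophomonad/Aminomon fell (-0.51 ± 0.15, adjusted p = 0.0391) and 17_D2CL_Syntropomonad/Aminomona stood at -0.48 ± 0.16 (adjusted p = 0.0517). Probes for a Bacteroidetes member (spelled Bacteriodetes in the files, -0.72 ± 0.17, adjusted p = 0.0164) and Dictyoglomus (-0.80 ± 0.16, adjusted p = 0.00684) fell. Both calls ended with processed ratios, in the Cy5 channel alone, in the authors' table and with slide row as a covariate, and the former also under 3 further settings. Over all settings the values came as near to 0 as -0.045 and -0.19, whereas with the covariate they were -0.81 ± 0.26 and -0.94 ± 0.22. Of 3 probes naming Bacteroides, 2 fell (-0.71 and -0.55) and 1 did not pass (-0.46). The median over the 61 probes was -0.11 while their mean was 0.18, and the list did not pass (adjusted p = 0.512, and adjusted p = 0.850 with an estimated correlation). With slide row as a covariate the median was -0.14, and with median centring in place of loess it was -0.64, where the list passed as lower. It was 0.10 with processed ratios, 0.040 in the Cy5 channel alone and -0.021 without replicate 3 of 2 days.

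**Figure D2:**
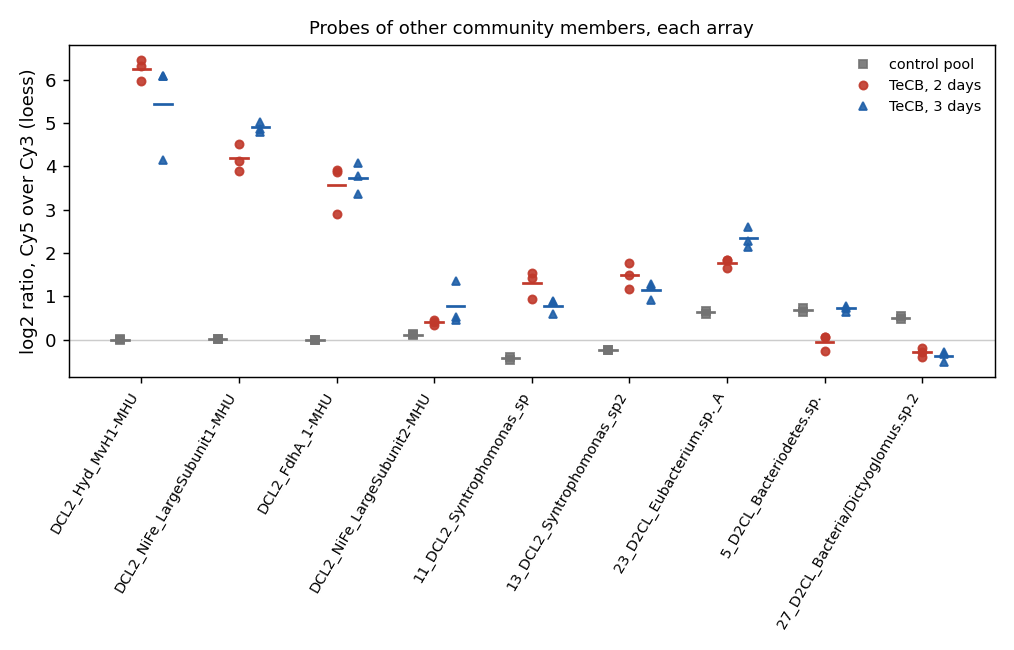
Log2 ratio of Cy5 over Cy3 after loess (vertical axis) for 9 probes of other community members (horizontal axis), with grey squares for the 2 control arrays, red circles for the 3 samples of 2 days, blue triangles for the 3 samples of 3 days and bars for group means. The probes Hyd_MvH1-MHU, NiFe_LargeSubunit1-MHU and FdhA_1-MHU lie far above the control arrays in all 6 TeCB samples, whereas NiFe_LargeSubunit2-MHU stood at 0.30 at 2 days and 0.66 at 3 days relative to the control, which did not pass.

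In limma, 433 of the 1232 strain 195 probes tested changed at 2 days, 181 higher (41.8%) and 252 lower, and 146 of them by at least 2-fold (76 higher, 70 lower). All 2-day samples lay in slide row 1 and both control arrays in row 2, so no within-row value exists. With slide row as a covariate, 184 probes changed, DET1559 stood at 5.24, DET0180 at 4.09 and DET1532 at -3.91. DET0079 lost its call there at 3.23 (adjusted p = 0.0673, range 5.1e-06 to 0.0796 over its alternatives), and the covariate also ended the calls of DET0088 and DET0306, which were not well above background at 2 days, and of DET0173, DET0615, DET0728, DET0185, DET0186 and DET0187. The values of these last 6 there were 0.96, 0.92, -0.70, -0.40, 1.35 and 1.61. That of DET0185 came nearer to 0 and the other 5 stayed as large or grew, while the standard errors of the named calls that ended grew 1.20 to 1.60 times. The covariate rests on replicate 1 of 3 days set against the other 2 samples of that time. With only the 2 groups fitted, 10 of 25 named calls ended, among them those of DET0079, DET0088, DET0173, DET0615, DET0728, DET0860, DET0185, DET0186 and DET0187, and 155 probes changed. From the Cy5 channel alone 267 changed with 53.2% of them higher, and that scaling moved the median difference of all probes from -0.12 to -0.0068.

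The comparison of 3 days with the control posed the same question a day later. DET1559 again had the largest rise of a strain 195 probe, at 15.2-fold (3.93 ± 0.35, n = 3 against 1 pooled sample, adjusted p = 6.2e-04), and DET0180 rose 4.61-fold (2.21 ± 0.27, adjusted p = 0.00277). DET1545, a reductive dehalogenase that had not passed at 2 days, rose 2.58-fold (1.37 ± 0.33, adjusted p = 0.0292). DET0079 stood at 1.39 ± 0.64 and did not pass (adjusted p = 0.168), nor did DET0318 at 0.31 ± 0.20 (adjusted p = 0.311). In the stretch beside DET1559, DET1556 rose by log2 2.05 ± 0.26 (adjusted p = 0.00312), and DET1560 stood at 0.85 ± 0.26 (adjusted p = 0.0624). The deepest falls among loci were those of DET1532 (-3.81 ± 0.19, adjusted p = 7.4e-05) and DET0023 (-3.06 ± 0.40, adjusted p = 0.00312).

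Of the 9 reductive dehalogenases tested, 3 rose at 3 days (DET0180, DET1545 and DET1559), 1 fell (DET0306) and 5 did not pass, with the same counts adjusted over the list alone. The list had a median of 0.47 and passed as higher than other genes (adjusted p = 0.0408), a call not kept at adjusted p = 0.294 with an estimated correlation. The call was also lost with processed ratios, with median centring, in the Cy5 channel alone (medians 0.49, 0.37 and 0.67) and without control array 2 (0.45). Its median was 0.47 with slide row as a covariate and 0.47 within slide row 2. Over all 18 members, with no filter on dim probes, the median was -0.061 and the list did not pass. DET0306, not well above background in any 3-day sample, was at least 1.44-fold lower (adjusted p = 0.0203), a call lost without replicate 2 or 3 of 3 days (fitted at -0.66 and -0.73) and in the authors' table. Without control arrays it was fitted at -0.42, short of its bound (log2 -0.52). DET1545 lost its call without replicate 1, 2 or 3 of 3 days (1.36, 1.30 and 1.44), in the Cy5 channel alone and in the authors' table. Without replicate 3 of 2 days, which enters the shared estimate of the spread, DET0079 (1.39), DET0088 (-0.53) and DET0173 (0.47) passed.

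None of the 17 hydrogenases changed at 3 days in limma (0 rose and 0 fell, also adjusted over the list alone; 2 rose and 1 fell at an unadjusted level of 0.05). Their median was 0.16 (adjusted p = 0.348, and adjusted p = 0.658 with an estimated correlation), or 0.24 both with slide row as a covariate and within row 2, 0.070 without replicate 2 of 3 days, and -0.053 over all 26 with no filter on dim probes. DET0186 (1.24 ± 0.35, adjusted p = 0.0461) and DET0187 (1.12 ± 0.31, adjusted p = 0.0464) rose, and DET0185 stood at -0.37. Adjusted over the list alone 2 rose and 1 fell. Both calls ended without replicate 2 of 2 days or without any 1 sample of 3 days (1.01 to 1.30), and with no filter, with a strict filter on dim probes and with a variance trend. That of DET0186 also ended with processed ratios, in the Cy5 channel alone and in the authors' table (1.06 to 1.30 over all its settings). The formate dehydrogenase-like list had a median of 1.12 (adjusted p = 0.249, and adjusted p = 0.616 with an estimated correlation), or 1.20 both with slide row as a covariate and within row 2. Of the transfer RNA probes, 28 fell, 0 rose in limma (0 also at an unadjusted level of 0.05) and 13 did not pass, with a median of -0.79. tRNA-Ala-1 fell by 2.41 on the log2 scale (SE 0.16, adjusted p = 2.2e-04), tRNA-Lys-1 was at least 6.84-fold lower (adjusted p = 2.2e-04; fitted short of that bound of log2 -2.77 after scaling between arrays and with median centring, at -2.33 and -2.72), and the 16S, 23S and 5S probes fell (-1.35, -1.75 and -1.96).

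Of the 61 community probes, 13 rose, 2 fell and 46 did not pass at 3 days. Hyd_MvH1-MHU, NiFe_LargeSubunit1-MHU and FdhA_1-MHU were at least 24.8-fold, at least 27.9-fold and at least 5.08-fold higher than in the control (adjusted p = 9.1e-04, 3.3e-06 and 7.1e-04). NiFe_LargeSubunit1-MHU was fitted below its bound (log2 4.80) after scaling between arrays (4.27) and with median centring (4.59). FdhA_2-MHU stood at -0.57 ± 0.23 and did not pass (adjusted p = 0.111). Eubacterium.sp._A (1.71 ± 0.20, adjusted p = 7.1e-04), Acetovibrio (1.24 ± 0.19, adjusted p = 0.00308) and Methanospirillum, a methanogen that uses hydrogen and formate (1.19 ± 0.20, adjusted p = 0.00309), rose in their ribosomal probes. These rises were not followed under the alternatives, so how far they depend on the normalization is unknown. The 4 probes that name Eubacterium in short beside other genera did not pass (0.43, -0.30, 0.46 and 0.42). Dictyoglomus (-0.89 ± 0.16, adjusted p = 0.00404) and Anaerolinea (-0.68 ± 0.19, adjusted p = 0.0379) fell, the latter not past the threshold without replicate 2 of 2 days, replicate 2 of 3 days or control array 1 (-0.64 to -0.72). Both calls ended with processed ratios, in the Cy5 channel alone and in the authors' table, where the values came as near to 0 as -0.33 and -0.28, and a second probe, Anaerolinea.sp.2, stood at -0.44 ± 0.22 (adjusted p = 0.146). The list had a median of 0.16 and passed as higher (adjusted p = 7.5e-04), a call not kept at adjusted p = 0.616 with an estimated correlation. Its median was 0.19 with slide row as a covariate and within row 2, and -0.30 with median centring in place of loess, where the list did not pass. It was 0.24 with processed ratios, 0.092 without replicate 3 of 3 days and 0.072 in the Cy5 channel alone, where the list did not pass.

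At 3 days, 217 of 1232 strain 195 probes changed, 70 higher (32.3%) and 147 lower, 85 of them by at least 2-fold (32 higher, 53 lower). The share of higher calls was 45.8% of 118 from the Cy5 channel alone, 43.0% of 107 in the authors' averaged Cy5 table and 42.8% of 250 from the scanner's processed ratios. The count was 141 without replicate 2 and 431 without replicate 3 of 2 days, and 143, 90 and 76 without replicates 1, 2 and 3 of 3 days. With slide row as a covariate 143 changed, the same fit as without replicate 1 of 3 days, since no other sample of that time lies in row 1. DET1559 stood at 4.04, DET0180 at 2.40, DET1532 at -3.79 and DET0023 at -3.11, the same values as within row 2, while DET1545 at 1.36, DET0186 at 1.30 and DET0187 at 1.20 lost their calls with standard errors 1.14 to 1.18 times as large. Within row 2 alone, which holds 2 of the 3-day samples and the control and leaves 1 residual degree of freedom, 669 changed.

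Both comparisons share the control sample. They called 180 probes in the same direction, 57 higher and 123 lower, and 0 in opposite directions (340 and 5 at an unadjusted level of 0.05 in both). Simulated unchanged groups sharing 1 control gave 0.03 probes in the same direction on average over 100 simulations, and independent lists of these sizes would share 10.3 higher and 30.1 lower. The log2 differences of the 2 comparisons correlated across probes at r = 0.862, against 0.750 in the simulations, with a covariance of 0.395 against 0.0421. Without control arrays, with ratios set against 0, 571 probes were shared. Those ratios still share the reference pool in Cy3 and keep the dye effect, so that count does not remove the sharing. The scatter of both comparisons shows DET1559 and DET1532 at the ends of this range.

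**Figure D3:**
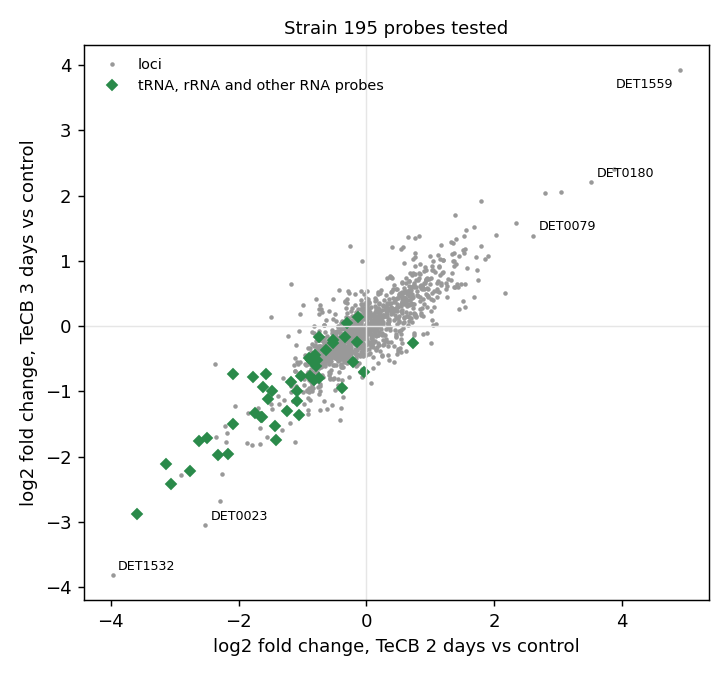
Log2 fold change at 3 days against the control (vertical axis) over that at 2 days against the control (horizontal axis) for the 1232 strain 195 probes tested, with grey points for loci and green diamonds for transfer, ribosomal and other stable RNAs. DET1559 lies at 4.91 and 3.93, DET1532 at -3.97 and -3.81, and most transfer RNAs lie below 0 on both axes.

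The comparison of 3 days with 2 days asked which levels differed between the times, n = 3 against 3, with the reference cancelling. The reductive dehalogenases DET0180 (-1.31 ± 0.19, adjusted p = 0.00706) and DET1559 (-0.98 ± 0.25, adjusted p = 0.0373) were lower at 3 days. So was DET1557, in the stretch beside DET1559 (-1.46 ± 0.12, adjusted p = 0.00157), and DET1448 fell 2.41-fold (-1.27 ± 0.18, adjusted p = 0.00624). DET0272 rose 3.54-fold (1.82 ± 0.21, adjusted p = 0.00295), and DET0183, not well above background in any 2-day sample, was at least 2.16-fold higher at 3 days (adjusted p = 0.00157). For each of these 6 loci the replicates of the 2 times did not overlap. The naming rule required this of the largest changes, so it lends them no support. Chance gives it for 10% of genes with 3 samples against 3. Among transfer RNA probes 15 rose, 1 fell (tRNA-Thr-1, -0.98 ± 0.13, adjusted p = 0.00493) and 25 did not pass, with tRNA-Lys-2 at 1.36 ± 0.13 (adjusted p = 0.00214) and a median of 0.32.

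Of the 9 reductive dehalogenases, 0 rose and 2 fell between the times and 7 did not pass, whereas 2 rose and 4 fell adjusted over the list alone (the same 2 and 4 at an unadjusted level of 0.05 in limma). The test of the list pointed lower (adjusted p = 0.638, and adjusted p = 0.865 with an estimated correlation) while its median was 0.14, or 0.050 with the member not well above background at its bound. That median was 0.11 with slide row as a covariate and within row 1, settings that give the same values by construction. It was 0.037 without replicate 1 and -0.11 without replicate 3 of 2 days. DET1559 lost its call without replicate 2 of 2 days (-1.01) or without replicate 1, 2 or 3 of 3 days (-0.87, -1.11 and -0.95), in the Cy5 channel alone and in the authors' table, as did both DET1559 and DET0180 after scaling between arrays (-0.11 and -0.66). None of the 17 hydrogenases changed (0 in limma, also adjusted over the list alone; 1 rose and 3 fell at an unadjusted level of 0.05). Their median was -0.074 (adjusted p = 0.638, and adjusted p = 0.865 with an estimated correlation), 0.035 and -0.24 without replicates 3 and 1 of 2 days, -0.022 and -0.14 without replicates 1 and 2 of 3 days, and -0.18 with slide row as a covariate and within row 1. None of the 3 formate dehydrogenase-like loci changed (0 in limma, 0 adjusted over the list alone and 0 at an unadjusted level of 0.05). Their median was 0.075 (adjusted p = 0.823, and adjusted p = 0.897 with an estimated correlation). It was -0.046 with slide row as a covariate and within row 1, -0.16, 0.038 and 0.29 without replicates 1, 2 and 3 of 2 days, and 0.14 and -0.016 without replicates 1 and 2 of 3 days.

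Of the 61 community probes, 23 rose, 5 fell and 33 did not pass between 2 and 3 days. Sulfuricurvum (1.00 ± 0.13), Acetovibrio (0.91 ± 0.14) and Nitrospira_sp2 (0.79 ± 0.11) rose (all adjusted p = 0.00230), and Methanospirillum rose by 0.78 ± 0.14 (adjusted p = 0.00455). The probes named sporomusakb1 (-0.77 ± 0.14, adjusted p = 0.00472) and Soehngenia.sp._a (-0.70 ± 0.14, adjusted p = 0.00587) fell, whereas another Soehngenia probe, Soehngenia.sp_b, rose (0.62 ± 0.16, adjusted p = 0.0131). Of 2 more Soehngenia probes, 1 fell (-0.65, adjusted p = 0.0119) and 1 did not pass (-0.26). None of these probes was followed singly under the alternatives. The list had a median of 0.24 and passed as higher (adjusted p = 1.1e-04), a call not kept at adjusted p = 0.865 with an estimated correlation. Its median was 0.25 with slide row as a covariate and within row 1. These 2 values are the same by construction, and row 1 holds only 1 sample of 3 days. The median was 0.15 without replicate 3 of 3 days and 0.099 in the Cy5 channel alone, where the list did not pass.

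Between the times 189 of 1232 strain 195 probes changed, 91 higher (48.1%) and 98 lower, 22 of them by at least 2-fold (12 higher, 10 lower). With median centring in place of loess 60.7% of 196 were higher. With slide row as a covariate 22 changed, 19 of them among the 189. DET0180 at -1.69, DET1557 at -1.53 and DET0183 at 1.63 kept their calls, whereas DET1559 at -1.20, DET0272 at 1.62 and DET1448 at -1.42 were not called, the standard errors of the named calls that ended growing 1.44 to 1.59 times. Within row 1 these log2 values were the same by construction, since both settings set replicate 1 of 3 days alone against 2 days. In row 1 alone, which holds 1 sample of 3 days, limma called 0 (221 at an unadjusted level of 0.05). The count was 36 without replicate 2 of 2 days and 61, 79 and 34 without replicates 1, 2 and 3 of 3 days.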

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

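Of the tests in this part, the splits of the samples and the effect of loess on transfer RNA were planned before their results were seen; those of the MHU probes, of uniform loss of small RNA and of DET0251 to DET0254 were chosen only afterwards. By limma's test of the difference between the times, the change from the control differed between 2 and 3 days for 189 strain 195 probes, of which 2 were well above background in no TeCB sample. The 10 splits of the 6 TeCB samples into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 189, and the highest of the others gave 0.

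The same test of the difference singled out 10 of the probes named for the control comparisons that were well above background in TeCB samples. Those with a smaller rise at 3 days were the reductive dehalogenases DET0180 (3 days minus 2 days, -1.31 ± 0.19, adjusted p = 0.00706) and DET1559 (-0.98 ± 0.25, adjusted p = 0.0373), with DET1557 (-1.46 ± 0.12, adjusted p = 0.00157) and DET1556 (-0.997 ± 0.187, adjusted p = 0.0139) from the stretch beside DET1559. Transfer RNAs lay closer to the control at 3 days, by 0.64 for tRNA-Ala-1, 0.54 for tRNA-Val-2 and 0.86 for tRNA-Val-3 (adjusted p = 0.00706 to 0.0185). tRNA-Ser-1 was fitted at 1.02 (adjusted p = 0.00249), a size that rests on 2-day signals not well above background. Among community probes, Bacteriodetes rose by 0.77 ± 0.12 between the times (adjusted p = 0.00284) and NiFe_LargeSubunit1-MHU by 0.71 ± 0.17 (adjusted p = 0.00923).

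Hyd_MvH1-MHU, NiFe_LargeSubunit1-MHU and FdhA_1-MHU were far above the control at both times. An artefact of the spots or of both dyes stays open: Cy3 was well above background in 0 of 18 pairs of probe and TeCB array, but the probes were picked for a high ratio over a pool below background, which leaves that value little room. For both hydrogenase probes, more cells of the same methanogen alone are argued against only if a comparator probe comes from that organism. That origin is not shown. The 2 comparators, the Methanospirillum ribosomal probe and NiFe_LargeSubunit2-MHU, reached at most 0.94 at 2 days and 1.58 at 3 days (estimate plus 2 SE). The bounds of the rises, less 2 SE, lay at least 1.68 above that. The Methanospirillum probe had a mean log2 intensity of 17.9, near the 18.2 of the brightest community probe, spirochetekb1. Whether its rise was compressed there was not tested. NiFe_LargeSubunit2-MHU lay at 13.9. For FdhA_1-MHU more cells alone stay open, since its bound less 2 SE lay 0.46 above the limit at 2 days but at -0.080 relative to it at 3 days. Also open is which organism these transcripts came from, since the probe names do not spell out MHU, and whether feeding, TeCB, its solvent or the bottles mattered.

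Transfer RNA probes of strain 195 lay below the control, with medians of -1.08 at 2 days and -0.79 at 3 days. As the only cause, uniform loss of small RNA from the TeCB extracts is argued against by the falls of the 16S and 23S probes. The spread over the transfer RNA probes, at least 4.38 times their median standard error, also argues against it. A common loss added to other differences between transfer RNAs stays open, since it would leave that spread unchanged. The loess normalization is argued against by the medians with median centring in its place (-1.22 and -0.84). Cy5 alone (-1.08 and -0.79) was free of that loess but not of dye normalization, which the scanner had already applied, so it decides less. The value nearest to 0 over both settings was -0.79. The Luciferase probe, whose purpose the files do not state, lay at -1.15 and -0.97, a shift of about the size of the transfer RNA medians. A larger share of messenger RNA in the labelled RNA may lower stable RNAs and the Luciferase signal relative to loci in all these scalings. This stays open, as do a loss that differs between transfer RNAs and a biological difference between fed and starved cells.

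The 4 loci with neighbouring tags DET0251 to DET0254 were higher at 3 days than at 2 days (1.23, 1.49, 1.31 and 1.01, adjusted p = 0.00157, 0.0129, 0.00865 and 0.0324), DET0252 losing its call without replicate 2 of 2 days (1.41) or replicate 1, 2 or 3 of 3 days (1.58, 1.39 and 1.51). Signal near background is argued against, since 0 of the pairs of locus and TeCB array were below the detection limit. Position on the slide cannot be told apart from time: within row 1 the median difference was 1.23 (1.15, 1.32, 1.33 and 1.01 for the loci), but that row holds only 1 sample of 3 days, and with slide row as a covariate DET0251 alone kept its call. A change with time after feeding may stand behind the difference and stays open, untested.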

How the results depend on the processing

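Slide row as a covariate or alone, the loess on strain 195 loci only and outlier spots kept were chosen after the data had been seen. The main counts were 433 probes for 2 days with the control, 217 for 3 days with the control and 189 between the times. Of the 56 calls of named genes and probes, 0 turned direction under any setting; 36 passed with slide row as a covariate, 45 each without replicate 2 of 2 days, replicate 2 of 3 days or replicate 3 of 3 days, 49 to 56 without another array, 37 of 40 with a strict filter on dim probes, 44 in the authors' table, 45 in Cy5 alone, 49 with processed ratios, and 53 to 56 with no background correction, offset 10, median centring, scaling between arrays, the median of spots, the variance trend, outlier spots kept, no filter, the replicate block or the loess on strain 195 loci. For values given without a call, DET0318 turned to -0.024 (median centring) and -0.24 (scaling between arrays) at 2 days and to -0.012 (scaling) at 3 days, and DET0088 to 0.027 at 3 days without control arrays. Where nothing is said, the cause was not tested.

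In the order of the comparisons, counts were 267, 118 and 99 in Cy5 alone, 251, 107 and 88 in the authors' table, and 184, 143 and 22 with slide row as a covariate, which spends a degree of freedom. A fold of at least 2, a stricter rule by construction, left 146, 85 and 22. Scaling between arrays gave 678 and 620 in the control comparisons, no control arrays 813 and 744, and the control arrays as separate samples, which counts technical replicates as independent, 700 and 500. Only the 2 groups compared gave 155 and 475, and at 2 days kept 15 of 25 named calls. Slide row 2 alone gave 669 for 3 days with the control, and slide row 1 alone 0 between the times (limma; 221 at an unadjusted level of 0.05, with 0 of 11 named calls kept), with fewer samples by construction. For 3 days with the control, slide row as a covariate is the same fit as leaving out replicate 1 of 3 days. Leaving out 1 array gave 298 to 527 at 2 days, 76 (without replicate 3 of 3 days) to 431 (without replicate 3 of 2 days) at 3 days, and 34 to 280 between the times for the same 2 arrays. The replicate block gave 445, 236 and 218; the replicate numbers do not pair the samples of the 2 times (r of -0.37 to 0.31 between like numbers across probes). Without control arrays 571 probes overlapped between the control comparisons, against 180, though those ratios still share the Cy3 pool and the dye effect. The overlap was 175 to 189 without 1 control array.

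Of 4 lists, 0 passed at 2 days (limma's camera; 1 at an unadjusted level of 0.05), but 1 with median centring, where the community test turned from higher to lower (median -0.64, against -0.11), and 1 with the replicate block. That median turned to 0.10 with processed ratios and 0.040 in Cy5 alone. At 3 days 2 passed; 1 did with processed ratios and with no filter (where the reductive dehalogenases, with all 18 members, lost their call at a median of -0.061), 0 with median centring (community median -0.30), in Cy5 alone and with an estimated correlation, and 1 to 2 without 1 array (1 without control array 2). Between the times 1 passed, and 0 in Cy5 alone and with an estimated correlation. The formate dehydrogenase-like median between the times turned from 0.075 to -0.046 with slide row as a covariate and -0.046 in row 1 alone, and ranged from -0.16 to 0.29 without 1 array; that of the hydrogenases ranged from -0.24 to 0.035, against -0.074.

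A block for slide or scan date was not run, since all arrays share 1 slide and 1 scan, nor was the brightest probe per gene, since each gene has 1 probe name. Signal over background left 9 of 18 reductive dehalogenases, 9 of 26 hydrogenases and 324 loci untested.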

Other observations

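The loci and probes in this part were chosen after their values were seen and were not followed under the alternatives. Beside DET0079, DET0078 rose at 2 days (1.74 ± 0.56, adjusted p = 0.0453) and stood at 0.71 ± 0.56 at 3 days (adjusted p = 0.393). Beside DET0180, DET0181 was at least 1.68-fold higher at 2 days (adjusted p = 0.00245), with no control array well above background for it. On either side of the stretch DET1556 to DET1560, DET1555 stood at -0.12 ± 0.17 and DET1561 at 0.065 ± 0.22 at 2 days. The probe for the RNA of ribonuclease P fell at both times (-1.42 ± 0.24 and -1.53 ± 0.24, adjusted p = 0.00524 and 0.00756).

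Of the further community probes, acetobacteriumkb1 rose at 2 days (0.77, adjusted p = 0.00574), sporomusakb1 rose (0.75, adjusted p = 0.0230) and syntrophusKB1 fell (-0.66, adjusted p = 0.0245). Nitrospira_sp2 fell at 2 days (-0.63, adjusted p = 0.0164) and stood at 0.16 at 3 days. Sulfuricurvum stood at -0.11 at 2 days and rose at 3 days (0.89, adjusted p = 0.00701). Both Syntrophomonas probes that rose at 2 days also rose at 3 days (1.22 and 1.39, adjusted p = 0.00702 and 0.00404), and the other 3 Syntrophomonas probes did not pass at 3 days (-0.043, -0.42 and -0.43).

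In the authors' table of averaged Cy5 intensities, 6 columns matched their own array over 1672 shared probe names (within 1e-06 on the log2 scale), and the 2 control columns held each other's values.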
